A study of Shiraia bambusicola with 3 samples.

How the data were processed

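RNA was sequenced from hyphae of Shiraia bambusicola, an ascomycete fungus that grows on bamboo and makes the perylenequinone pigments known as hypocrellins. The series held 3 libraries, titled B1, R1 and D1, which were read as 3 groups (B, R and D) of 1 library each. Per the labels, B1 was wild type and R1 and D1 were of an experimental type, and the meaning of the letters B, R and D was not given in the sources used here. R1 and D1 shared that label but had different titles, so they were not treated as replicates of each other. Their age labels differed too, at day 22 for D1 and day 21 for both R1 and B1. Parts of the submitters' record described other organisms. The series title spoke of cotton under insect attack, the design text of Arabidopsis under heat, and the sample ages were given in days after birth, which has no clear meaning for a fungus. None of these statements was used to form groups or comparisons. The labels' protocol mentioned digestion of polysomes with RNase, TRIzol extraction of total RNA, spike-in RNA and a kit that depletes plant ribosomal RNA, and which of these steps were applied to these 3 libraries could not be told from the labels.

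One table with 12515 features and 1 column per library was deposited. The deposited values were taken as TPM (transcript abundance scaled for feature length and to a fixed library total). Each column summed to 1000000 within rounding to 2 decimals. The values did not fall on the shared steps that CPM values of whole counts give at limited depth. Of the 99 possible values between 0 and 1 TPM, 91 occurred in B1, 80 in R1 and 79 in D1. CPM of fractional counts or of very deep libraries would show no such steps either, so the unit is an inference. All 12515 feature IDs had the form that the Trinity de novo assembler writes (cluster, component and gene number), per the file's first column. Bowtie 1.0.0 was named in the submitters' processing notes. The assembly settings, the quantifier and any filter were not given in the sources used here. The feature lengths, the read counts and the depth of the libraries were not known, so no counting intervals or detection limits could be given, and a value of 0 was read only as a feature listed at 0. No column was left out.

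The table paired no feature with a gene name or description, and no genome or annotation was used here. The 24 gene lists fixed before the data were examined (polyketide synthases, light sensing, antioxidant enzymes, ribosomal proteins, markers of reads from other sources and others) were defined on names and descriptions and could therefore not be applied, so features are given by ID. Features of one Trinity component can be pieces, alleles or isoforms of one gene or near-identical paralogs, and 2900 of the 12515 features shared a component with another feature.

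Log2 ratios between libraries were differences of log2(TPM + 1). This scale understates the change of features with low values. Features of at least 1 TPM in at least 1 library were kept, which left 12370, and 122 features were listed at 0 in all 3 libraries. Features at least 4-fold apart were counted in each direction, with 2-fold counts beside them. The values were compared as deposited, and also relative to the median log2 ratio of the kept features, a step added after the data had been seen. The medians against B1 were above 0 and were subtracted after 1 TPM had been added. A low feature at 0 in R1 or D1 therefore passes as lower than B1 more readily than the reverse. No test was run between libraries: with 1 library per group there are no residual degrees of freedom, and the differences describe these libraries, not the conditions. Similarity was given as Pearson and Spearman correlations across features, which are not independent replicates. The variance particular to a library was computed as the covariance, across features, of its log2 differences from the other 2 libraries, over all kept features and in quintiles of mean log2 level from which TRINITY_DN3092_c1_g1 was left out. It is negative where a library tends to lie between the others. Because R1 and D1 were both set against B1, 100 data sets with no effect were simulated, with deviations for all 3 libraries drawn from the R1 to D1 differences divided by the square root of 2, within 20 bins of mean level. This takes the whole of the R1 to D1 difference as chance. Differences of 2 such draws keep the variance but hold fewer extreme values, and the drawn deviations are symmetric with no floor at 0. The simulation was repeated under 5 of the alternative settings, a step added after the data had been seen.

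Before the data were examined, the rule for the features to name was fixed: for each of the 3 pairs of libraries, the 2 features with the largest log2 ratio in each direction among those of at least 10 TPM in the higher library, where no names are available. TRINITY_DN3092_c1_g1 was named in addition because of its share of the B1 total, after its values had been seen. The alternatives fixed beforehand were median of ratios scaling, upper quartile scaling, no filter, a filter of 10 TPM, a pseudocount of 0.1 TPM and an 8-fold threshold. The planned scaling and filter alternatives for the gene lists were not run, since the lists had no members.

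Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with figures drawn in matplotlib 3.10.9. The counting of features was tested on simulated data for the R against B comparison, with 200 of the features changed, 100 raised and 100 lowered, among 12088 features. The simulated libraries had no spread between them, so this checked the arithmetic of the counting and the rescaling, and says nothing about false calls. The simulation with no effect described above, which does hold a spread, gave between 320 and 323 features at least 4-fold apart in each direction on average when set against B1.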

Results

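The transcriptome of Shiraia bambusicola hyphae was measured in 3 libraries, titled B1, R1 and D1, each the only library of its group. B1 carried the wild type label and served as the reference, and R1 and D1 carried an experimental label that the record does not explain. The table listed 12515 features of a de novo assembly, which stand for genes but carry no gene names. Values above 0 were listed for 11601 features in B1, 11869 in R1 and 11614 in D1. At least 1 TPM was listed for 10784 features in B1, 11510 in R1 and 11257 in D1. The read depth behind these values was unknown, and without replicates none of the differences below has an error or a replicate check.

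A single feature dominated B1. TRINITY_DN3092_c1_g1 stood at 160741 TPM in B1, which was 16.1% of that library's total, against 21340 TPM (2.13%) in R1 and 20083 TPM (2.01%) in D1. Its level was thus 7.53-fold lower in R1 and 8.0-fold lower in D1 than in B1. It was the most abundant feature of B1, the second most abundant of R1 and the third most abundant of D1. The 10 most abundant features together took 23.7% of the B1 total, 10.2% of R1 and 12.4% of D1. With the highest feature of each library set aside, the next 10 took 9.62% of the remainder in B1, 8.72% in R1 and 10.0% in D1. The smallest number of features that made up 50% of the total was 179 in B1, 366 in R1 and 294 in D1. When TRINITY_DN3092_c1_g1 was left out, these numbers were 302, 390 and 311. The sets of 10 most abundant features had 6 members in common to all 3 libraries, and R1 and D1 shared 8. Of the 100 most abundant features, 77 were shared by R1 and D1, 65 by B1 and R1, and 67 by B1 and D1.

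In the comparison of R1 with B1, most features were listed somewhat higher in R1. The median of the 12370 kept features was 13.9 TPM in R1 and 10.1 TPM in B1, and the median log2 ratio of R1 over B1 was 0.48, or 1.39-fold. As deposited, 717 features were at least 4-fold higher and 376 at least 4-fold lower in R1, so that 65.6% of these features were higher. Many of these had low values. The lowest quintile by mean level (median 1.53 TPM) held 273 of the higher and 149 of the lower ones. The second (median 3.65 TPM) held 209 and 108, and the highest (median 134 TPM) held 60 and 33. Relative to the median ratio the balance turned: 372 features were at least 4-fold higher and 640 at least 4-fold lower, and 36.8% were higher. This turn depended on the pseudocount of 1 TPM. With a pseudocount of 0.1 TPM, 967 features were higher and 911 lower relative to the median. Libraries with no effect were simulated from the R1 to D1 differences. They held 320 higher and 322 lower features on average, with maxima of 370 and 357 in 100 draws. These maxima are not a firm bound, because the simulation thins extreme differences. D1 against R1, the pair taken as chance, itself held 369 higher and 314 lower features relative to its median. At 8-fold that pair held 128 higher and 86 lower, against simulated maxima of 94 and 99 for R1 against B1. Whether the higher count exceeded the simulated maximum depended on the processing: it was 191 against 123 with a filter of 10 TPM, 967 against 750 with a pseudocount of 0.1 TPM and 444 against 367 without TRINITY_DN3092_c1_g1, but 378 against 384 with no filter and 87 against 94 at 8-fold. At 2-fold, the counts were 3374 higher and 1134 lower as deposited, and 1600 higher and 1913 lower relative to the median. Within 2-fold of the median ratio lay 8857 features, or 71.6%. Among the 7437 features that reached 10 TPM in at least 1 library, 199 were at least 4-fold higher and 321 at least 4-fold lower relative to the same median.

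The features farthest apart between R1 and B1 were nearly absent in one library and at moderate or high levels in the other. TRINITY_DN2358_c0_g1 was listed at 0.29 TPM in B1 and 215 TPM in R1, a log2 ratio of 7.39. TRINITY_DN2802_c0_g1 was listed at 0.30 TPM in B1 and 90.6 TPM in R1, a log2 ratio of 6.14. In the other direction, TRINITY_DN980_c0_g1 ranked 31 in B1 with 2593 TPM and stood at 1.60 TPM in R1, a log2 ratio of -9.96. TRINITY_DN992_c0_g1 stood at 399.8 TPM in B1 and 0.57 TPM in R1, a log2 ratio of -8.0. Each of these 4 features was the sole member of its assembly cluster. Their sizes exceed any shift between the libraries' medians, but the lower value of each pair lies near the bottom of the range, where the ratio is poorly determined.

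**Figure D1:**
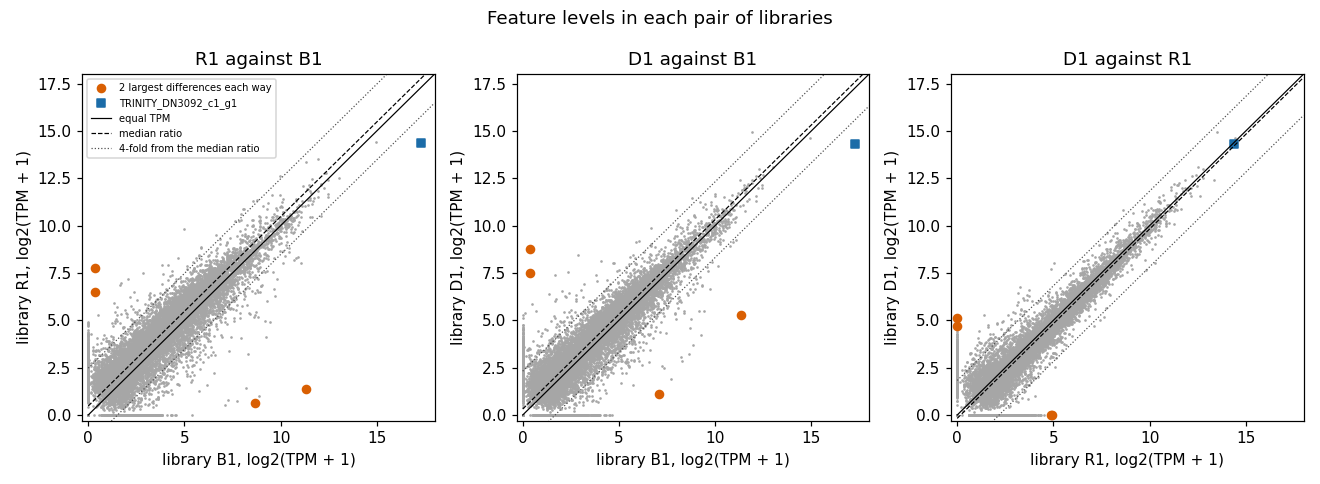
Levels of the 12370 kept features as log2(TPM + 1) in each pair of libraries, with 1 grey point per feature. Orange points are the 2 largest differences in each direction, the blue square is TRINITY_DN3092_c1_g1, and lines mark equal TPM (solid), the median ratio (dashed) and 4-fold from it (dotted). The cloud is tightest for D1 against R1, where 84.9% of features lie within 2-fold of the median ratio, against 71.6% for R1 against B1.

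The comparison of D1 with B1 gave a smaller shift of the median and some of the same extreme features. The median log2 ratio was 0.32, or 1.24-fold, with medians of 12.3 TPM in D1 and 10.1 TPM in B1. As deposited, 547 features were at least 4-fold higher and 382 at least 4-fold lower in D1, and 58.9% of these were higher. The lowest quintile by mean level held 214 of the higher and 180 of the lower ones. The second held 190 and 104, and the highest 34 and 26. Relative to the median ratio, 371 were higher and 556 lower, and 40.0% were higher. The simulation with no effect gave 322 higher and 323 lower on average, with maxima of 359 and 374. At 2-fold, 2233 features were higher and 1130 lower as deposited, and 1353 were higher and 1616 lower relative to the median. Within 2-fold of the median ratio lay 9401 features (76.0%). Among features that reached 10 TPM, 183 were at least 4-fold higher and 233 at least 4-fold lower relative to the same median. TRINITY_DN2358_c0_g1 and TRINITY_DN2802_c0_g1 were again the 2 largest increases, at 435 TPM and 180 TPM in D1, with log2 ratios of 8.40 and 7.12. TRINITY_DN980_c0_g1 was again the largest decrease, from 2593 TPM in B1 to 37.7 TPM in D1, a log2 ratio of -6.07. TRINITY_DN8907_c0_g1 followed, from 136.6 TPM in B1 to 1.18 TPM in D1, a log2 ratio of -5.98, and it was listed at 0.44 TPM in R1.

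**Figure D2:**
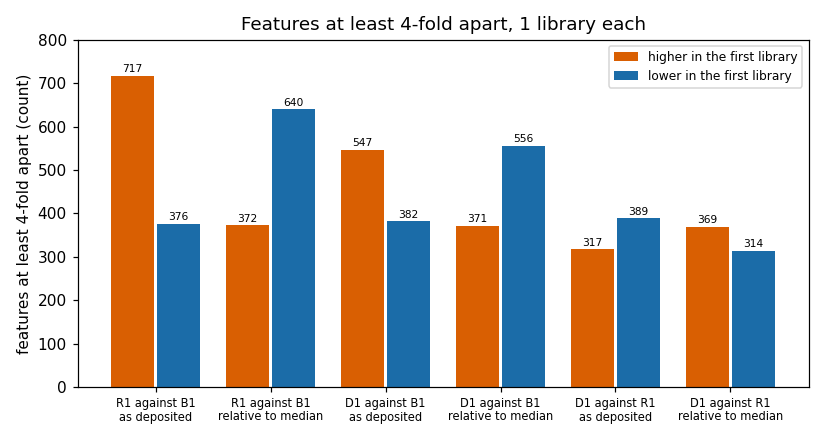
Number of features at least 4-fold higher (orange) or lower (blue) in the first library of each pair, among 12370 kept features, from values as deposited and relative to the median log2 ratio. The majority is higher in R1 and D1 than in B1 as deposited (717 and 547) and lower relative to the median (640 and 556). These counts use a pseudocount of 1 TPM. With 0.1 TPM, R1 against B1 relative to the median held 967 higher and 911 lower features. Each bar rests on 1 library per group.

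R1 and D1 were more alike than either was to B1. The median log2 ratio of D1 over R1 was -0.18. As deposited, 317 features were at least 4-fold higher and 389 at least 4-fold lower in D1. Most of these had low values. The lowest quintile by mean level (median 1.53 TPM) held 174 of the higher and 270 of the lower ones. The second (median 3.65 TPM) held 110 and 107, and the highest (median 134 TPM) held 3 and 3. Relative to the median, 369 were higher and 314 lower, and 10504 features (84.9%) lay within 2-fold. Among features that reached 10 TPM, 134 were at least 4-fold higher and 72 at least 4-fold lower relative to the median. The largest differences all involved a value of 0, so no fold is given. TRINITY_DN7372_c0_g1 was listed at 34.1 TPM in D1 and at 0 in both B1 and R1. TRINITY_DN3696_c0_g1 was listed at 24.7 TPM in D1, at 7.12 TPM in B1 and at 0 in R1. TRINITY_DN6145_c0_g2 and TRINITY_DN1089_c0_g2 were listed at 29.6 TPM and 28.5 TPM in R1 and at 0 in both B1 and D1. The last 3 of these shared their assembly component with 1 other feature each, so their reads may be split between near-identical sequences. No feature listed at 0 in one library exceeded 40.8 TPM in another. At 0 in B1 and at least 10 TPM in both R1 and D1 were 7 features, and the matching number was 3 for R1 and 3 for D1.

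Correlations across features gave the same order of similarity. Pearson's r of log2(TPM + 1) was 0.93 between R1 and D1, 0.90 between B1 and D1, and 0.89 between B1 and R1. Spearman's rho was 0.93, 0.89 and 0.88 in the same order. Of the variance between the libraries, 50.9% was particular to B1, 28.9% to R1 and 20.2% to D1. For the next counts, each library's own median log2 level was subtracted, in place of the median ratio. On that scale, 286 features were at least 4-fold higher in B1 than in both R1 and D1 while the latter 2 lay within 2-fold of each other, and 112 were at least 4-fold lower. The matching numbers were 144 higher and 92 lower for R1, and 137 higher and 80 lower for D1. These counts used a pseudocount of 1 TPM. Subtracting the medians, lowest in B1, makes a low feature pass more readily as higher in B1 than as lower. The counts were not rerun with 0.1 TPM. With that pseudocount, features at least 4-fold from B1 in both R1 and D1, relative to the median ratios, numbered 532 higher and 460 lower. With 1 TPM these were 128 and 339.

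The share of each library depended on the level of the features. In the lowest quintile by mean level, with a median of 1.53 TPM, the 3 libraries had similar variances of their own, 0.91 for B1, 1.01 for R1 and 0.93 for D1 in squared log2 units. In the highest quintile, with a median of 134 TPM, the values were 0.57 for B1, 0.20 for R1 and -0.0066 for D1. A value near 0 means that the differences of D1 from B1 and from R1 were uncorrelated across features. In that quintile the SD of the log2 ratio across features was 0.87 for R1 against B1, 0.75 for D1 against B1 and 0.44 for D1 against R1.

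**Figure D3:**
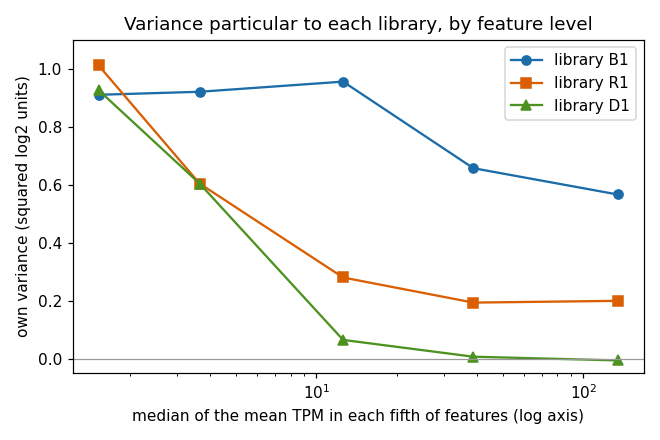
Variance particular to each library (covariance of its log2 differences from the other 2 libraries, in squared log2 units) in 5 groups of features of rising mean level (log axis, TPM), with 1 line per library. The lines lie at 0.91 to 1.01 in the lowest quintile. In the second, R1 and D1 are both at 0.60 and B1 is at 0.92. R1 and D1 part from the third quintile (0.28 and 0.064). In the highest, the values are 0.57 for B1, 0.20 for R1 and -0.0066 for D1.

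R1 and D1 differed from B1 partly in the same features. Relative to the median ratios, 128 features were at least 4-fold higher than in B1 in both R1 and D1, and 339 were at least 4-fold lower in both. No feature was 4-fold higher in one and 4-fold lower in the other (0 features). Independent lists of these sizes would share 11.2 higher and 28.8 lower features. Both comparisons use the same B1 library, however, and simulated libraries with no effect shared 107 higher and 109 lower features on average, with maxima of 133 and 137 in 100 draws. The number of shared lower features lay above the simulated maximum under each of the 6 settings simulated. This number was 196 against 56 with a filter of 10 TPM and 460 against 383 with a pseudocount of 0.1 TPM. As above, the maxima are not a firm bound, because the simulation thins extreme differences. The simulation also gave B1 the same spread as R1 and D1, so a larger spread of B1 from any source would give such an excess. All 6 settings used the same 3 libraries. The simulated deviations were symmetric with no floor at 0, while subtracting the medians favours the lower side among low features. How much of the excess on the lower side comes from this was not tested. The number of shared higher features lay below the simulated maximum here, but this depended on the processing. With the same setting applied to the simulation, the number of shared higher features was 85 against a maximum of 56 with a filter of 10 TPM, 532 against 390 with a pseudocount of 0.1 TPM, and 167 against 141 without TRINITY_DN3092_c1_g1. The correlation of the 2 sets of log2 ratios across features was 0.68, against 0.50 in the simulation, and the covariance was 0.81 against 0.39, a difference of 0.42. Both simulated values follow from the design of the simulation, which gives all 3 libraries equal spread. The observed covariance is by definition the variance particular to B1, so these values restate its share and are no separate comparison with chance. With 1 reference library the controls could not be split, so the whole excess may come from the B1 library itself.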

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

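Of 74 alternative values, 38 stayed close to the reported ones (counts within 1.5 times, other values within their 95% interval over features) and 36 moved. This split does not measure robustness. Features below 1 TPM in all libraries cannot be 4-fold apart once 1 TPM is added, so the as-deposited counts without a filter could not change. Higher and lower counts could also both stay close while the larger side turned. The larger side of the higher and lower counts turned under several settings. With a pseudocount of 1 TPM, scaling decided the balance of directions against B1. For R1, median of ratios scaling gave 455 features at least 4-fold higher and 595 lower, upper quartile scaling gave 479 and 578, and values relative to the median feature (chosen after seeing the data) gave 372 and 640, against 717 and 376 as deposited, because these scalings bring the median ratio to between 0 and 0.022. The share of higher features among those 4-fold apart was 65.6% as deposited, 43.3% with median of ratios and 45.3% with upper quartile scaling. For D1 against B1 the shares were 58.9%, 45.9% and 46.2%, and for D1 against R1 44.9%, 51.6% and 50.9%. Without the most abundant feature (also chosen after seeing the data) they were 57.3% for R1 and 50.4% for D1. A filter of 10 TPM, which tests fewer features, gave 354 higher and 193 lower for R1 against B1, 248 and 161 for D1 against B1, and 113 and 83 for D1 against R1, where the larger side changed from lower to higher. A pseudocount of 0.1, which widens the ratios of low features, gave 1356 and 641, 998 and 737, and 530 and 713. Relative to the median, that pseudocount gave 967 higher and 911 lower for R1 against B1, and 818 and 877 for D1 against B1. An 8-fold threshold gave 179 and 100, 169 and 101, and 98 and 112. Pearson's r with a filter of 10 TPM was 0.833 for R1 and B1, 0.861 for D1 and B1 and 0.924 for D1 and R1, and with a pseudocount of 0.1 it was 0.804, 0.818 and 0.842; R1 and D1 stayed the nearest pair in both. The share of variance particular to B1 was 62.1% with the filter of 10 TPM and 42.4% with the smaller pseudocount. Features higher than B1 in both R1 and D1 numbered 85 with the filter of 10 TPM, 532 with the pseudocount of 0.1 and 24 at 8-fold. Features lower in both numbered 196, 460 and 88 in the same order, so that with the smaller pseudocount the larger side was higher, against 128 higher and 339 lower as reported; without the most abundant feature the numbers were 167 and 346. No paired analysis was possible because each group held 1 library. No library could be left out for the same reason, and the alternatives for gene lists were not run. The unknown depth limits all values of low features.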

Other observations

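The tests that removed TRINITY_DN3092_c1_g1 alone, that looked for an even background and that bounded a mix were chosen after the result was seen, as was the comparison with opposite ratios, while the removal of all abundant features and the search for like ratios were set out before their results were known. Every pattern below rests on 1 library per group, so a difference between conditions and a difference between preparations are both open for each.

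The median feature was higher in R1 and D1 than in B1, and a candidate explanation is that TRINITY_DN3092_c1_g1 took so much of the B1 total that all else was pushed down. With that feature removed and each library rescaled, the median log2 ratio remained at 0.28 for R1 (bootstrap 95% interval over features 0.26 to 0.30) and 0.13 for D1 (0.11 to 0.14), so it was not the whole cause, although it accounted for part of the shift. With all 209 features of at least 1000 TPM removed, 0.23 remained for R1 and 0.15 for D1, so the abundant features as a set were not the whole cause either. An even background of reads in R1 would add the same TPM to every feature, but with TRINITY_DN3092_c1_g1 removed and the libraries rescaled the median difference of R1 minus B1 was 13.5 TPM in the highest quintile and 0.41 TPM in the lowest. A broader spread of transcription in R1, or a difference in library preparation, stays open.

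The share of TRINITY_DN3092_c1_g1 in B1 might come from an abundant RNA of another source in B1 that the assembly holds as several features, such as ribosomal RNA left after depletion. At least 3 other features with like ratios were required in advance, and 4 features of at least 100 TPM on average had both log2 ratios within 0.5 of its own. Among these, TRINITY_DN357_c0_g1 and TRINITY_DN357_c0_g2 shared a component, so they may be pieces of the same gene. However, 2 features lay at the opposite ratios, and the 4 features summed to 1144 TPM in B1 against 160741 TPM. The other feature of its cluster, TRINITY_DN3092_c0_g1, was listed at 3.09 TPM in B1 and 5.80 TPM in R1, so it did not follow. Without its sequence, such a source and a highly expressed gene of the fungus cannot be told apart.

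The variance particular to D1, as computed here, was near 0 among abundant features (-0.0066 in the highest quintile, against 0.57 for B1 and 0.20 for R1). Such a value is a net one, since features where D1 lies between B1 and R1 lower it. Relative to the library medians, D1 lay in the middle for 45.8% of all 12370 kept features. One possible explanation is that D1 is a mix that holds at least 10% of B1 RNA or reads. Such a mix would leave every feature at 10% of its B1 level or more, yet 10 of 1673 features of at least 100 TPM on average stood below 10%, 6 of them below 5% and 2 below 2%, with the lowest at 1.46%. Over the 78 such features at least 4-fold apart between R1 and B1 relative to the median, the B1 percentage a mix would need had a median of 8.45 (bootstrap 95% interval 2.42 to 15.9), which does not exclude 10%; it was 3.15 (2.29 to 12.6) for the 55 features higher in B1, 52.9 (-4.94 to 66.2) for the 23 higher in R1 and -0.90 for TRINITY_DN3092_c1_g1. The features below 10% argue against a mix of that size. The lowest of these would limit any carry-over of B1 to about 1.46% if its values were exact, which cannot be checked without replicates. TRINITY_DN8907_c0_g1, which averaged below 100 TPM, had a lower ratio of D1 over B1, at 0.0086, but its D1 value of 1.18 TPM was near the bottom of the range. The SD of the log2 ratio of D1 over R1 was 0.44 in the highest quintile. Whether a smaller carry-over could account for the pattern could not be told. The rest of D1 need not equal R1, and without replicates the SD between 2 like libraries is unknown. An intermediate condition of the culture was not tested and stays open.

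Features of one Trinity component changed together to a limited degree. Over 1206 pairs of features, 1 pair per component, Pearson's r of the log2 ratios of R1 over B1 was 0.23 and Spearman's rho 0.26, against -0.11 to 0.12 in 1000 random re-pairings. For D1 over R1, Pearson's r was 0.094, against a highest re-pairing of 0.090. Over the 103 pairs with both features at 10 TPM or more, r was 0.29 for R1 over B1, 0.30 for D1 over B1 and -0.013 for D1 over R1. No re-pairing was run for these 103 pairs. Fewer pairs give a wider range, so the ranges above do not apply to them. The 640 features at least 4-fold lower in R1 than in B1 relative to the median came from 611 assembly clusters, and the 372 higher ones from 369.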
